A study of Arabidopsis thaliana with 4 samples.

How the data were processed

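Root RNA of 4 samples was measured on single-colour Affymetrix ATH1 arrays, 1 array for each combination of nutrient solution (control or potassium-free) and time after transfer (48 h or 96 h). The deposited values are signal intensities on a linear scale, 1 per probe set and array, computed by the authors with MAS5, per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array as a whole. Its version and settings are not given in the sources used here. The 2% trimmed mean was 100.01 on each of the 4 arrays, so the deposited intensities had been scaled to a common level. That scaling assumes that most transcripts do not shift in 1 direction. The lowest signal on an array was between 0.0136 and 0.0175, and no value was missing. Array precision cannot be read from single values, so the number of arrays limits it. Nothing in the labels gives separate cultures. No group held a second array, so a p-value here does not measure the spread between like arrays. The residual behind it is the difference of the starvation effect between the times, with its spread shared across probe sets.

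Samples were grouped by their titles, and each group held 1 array. The 64 control probe sets were set aside, which left 22746. Each array was scaled to a 2% trimmed mean of 100, and log2(value + 16) was used throughout. Fold changes are on this log2(value + 16) scale, which understates the changes of dim probe sets. Probe sets were tested when their value reached the array's own 40th percentile on at least 2 of the 4 arrays. This kept 13998 probe sets and left out 8748.

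Probe sets were named through the platform annotation that came with the series. Exactly 1 gene was listed for 13513 probe sets, several genes for 503, and 8730 had no gene listed there. The Entrez identifiers of 13436 of the 13513 matched a gene of the RefSeq table of assembly TAIR10.1, whose symbol and locus were then used. The remaining 77 kept the annotation's name. No coordinates are given, because the authors' genome build is not given in the sources used here. Probe sets with several genes or without a listed gene are given by their identifier. Where a gene had several probe sets, the one with the highest mean was used. Of 75 such genes among the tested probe sets, 0 had probe sets of opposite sign with a mean starvation difference of at least 0.5 on the log2 scale, and no named gene was among the 75.

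Differences within a time are values without a test. Probe sets at least 2-fold higher or lower were counted for each time, for both times in the same direction and for opposite directions. The average starvation effect and the change from 48 h to 96 h were tested with limma 3.58.1 in R 4.3.3. The model had solution and time as terms and was fitted to all 4 arrays (lmFit, then eBayes with an intensity trend), with 1 residual degree of freedom per probe set. Real differences of the starvation effect between the times therefore count as error. The eBayes prior had 14.94 degrees of freedom, so the SE and p of a probe set rest mostly on the spread of other probe sets. Benjamini-Hochberg adjustment ran over the 13998 probe sets, with a threshold of 0.05. The fit was tested on simulated data with noise from the fitted spread, where 200 of the 13998 probe sets carried a known starvation effect. It recovered 98.5% of 2-fold changes with 34 false calls (14.7% of the calls) and 100% of 4-fold changes with 23 false calls (10.3%). The false share was above the nominal 5%, so adjusted p-values here may be too small. No simulation with fewer or no planted effects was run, so the false share among a smaller number of calls is not known. The planted effect was the same at both times, so the recovery does not carry over to effects that differ between them. The rule of at least 2-fold at both times recovered 28.5% of the planted 2-fold changes and 100% of the 4-fold ones.

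Before the data were examined, 33 gene lists with 536 genes were fixed. Of these genes, 51 had a named probe set and 32 passed the filter. Lists with at least 3 measured members, of which there were 3, were described by their median log2 difference. Its percentile was taken among 10000 random lists of the same size, drawn within 20 bins of mean expression. This describes the arrays and is not a test over replicates. The percentile was checked on simulated lists.

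The genes named in the text followed a rule fixed beforehand for probe sets with 1 annotated gene. It took the 12 highest and 12 lowest by the smaller of the 2 absolute starvation differences, with the same direction at both times. It also took the 5 highest and 5 lowest at each time, and the 8 highest and 8 lowest for 96 h against 48 h. The 10 genes with the smallest limma p were added for each effect, with up to 4 members of each list by their mean change. Certain potassium and nitrate transport genes were to be named always where measured, and none of them had a named probe set that passed the filter. Probe sets without a gene name were added after their values were seen.

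Alternatives fixed beforehand were pseudocounts of 1 and 64, quantile normalization, equal medians of log2 values, cyclic loess normalization, no filter, and a filter at the 60th percentile. Fold thresholds of 1.5 and 3 were tried for the counts. For limma, a fit without the other term, eBayes without trend and each array left out in turn were tried. Tables were made with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.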

Results

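Roots of Arabidopsis thaliana, accession Col-0, were profiled after the plants had been moved to a nutrient solution without potassium or to a fresh control solution. The plants were 4 to 5 weeks old and grown in hydroponic culture, that is, with their roots in liquid nutrient solution. RNA from roots was labelled with biotin and hybridised to Affymetrix ATH1 arrays, which carry 22810 probe sets. Each of the 4 arrays was a group of its own: control at 48 h, potassium-starved at 48 h, control at 96 h and potassium-starved at 96 h. There was 1 array per group and therefore no replicate check within a time. The number of arrays limits the precision of every value. In the starvation solution the potassium salts of the control solution were replaced by phosphoric and nitric acid, and the labels do not state whether the pH was set afterwards. The median MAS5 signal was 47.2 and 46.8 on the control and starved arrays at 48 h, and 47.0 and 47.8 at 96 h. Of 13998 probe sets that passed the filter on low values, 7587 had exactly 1 annotated gene, and these covered 7507 genes. Genes for the best-known potassium transporters and channels, among them HAK5, AKT1, SKOR and GORK, were not among the named probe sets. Probe sets without a listed gene were tested all the same, so those of these genes may be among them under an identifier. Nothing is said here of these genes by name.

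The first question was which transcripts differed between starved and control roots at both times. Averaged over 48 h and 96 h, transcripts for the glucosyltransferases UGT72E1 (AT3G50740) and UGT72E2 (AT5G66690) rose 1.74-fold and 1.75-fold in starved roots. The cineole synthase TPS-CIN (AT3G25830) rose 1.72-fold and the defensin PDF2.1 (AT2G02120) rose 1.97-fold. TPS-CIN has a near-identical tandem copy, so which copy its probe set measured is uncertain. The transcription factor WRKY53 (AT4G23810), a regulator of leaf senescence, fell 1.85-fold, and the expansin-like cell wall gene EXLA1 (AT3G45970) fell 2.05-fold. AT5G26130, which encodes a secreted protein of the CAP family, fell 2.36-fold. These calls hold for the main setting: all 11 named genes called for starvation lost the call with a pseudocount of 1, with equal medians, after cyclic loess normalization and without the filter. The adjusted p of each from limma reached 0.797 without the filter.

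Among named genes, those 3 falls were joined by AT1G50040, which fell 2.32-fold, and the rises by AT1G73120 (2.04-fold), the methyltransferase-family gene AT5G37990 (2.06-fold) and AT4G01390 (2.43-fold). Adjusted p-values from limma were 0.0141 for AT5G26130, 0.0142 for AT5G37990, 0.0183 for EXLA1, 0.0189 for AT1G73120 and 0.0245 for PDF2.1 and AT1G50040. They were 0.0271 for WRKY53 and AT4G01390, 0.0393 for UGT72E1, 0.0430 for UGT72E2 and 0.0481 for TPS-CIN. The log2 differences at 48 h and 96 h were 0.87 and 0.73 for UGT72E1, 0.68 and 0.93 for UGT72E2, 0.66 and 1.3 for PDF2.1, and -0.81 and -0.97 for WRKY53. They were unequal for AT4G01390 (0.62 and 1.94) and AT1G50040 (-1.69 and -0.74), and EXLA1 was 2.58-fold and 1.63-fold lower, so each of these means joins a smaller and a larger difference. The mean log2 difference was 0.80 ± 0.15 (SE) for UGT72E1 and -0.89 ± 0.16 (SE) for WRKY53, each from 2 arrays per solution. These SEs rest mostly on a spread shared across probe sets, and not on replicates of the gene itself. AT5G26130 measured 1714 in the control and 1007 in the starved roots at 48 h, and 159.9 and 37.4 at 96 h. PDF2.1 measured 389 and 624 at 48 h, and 60.3 and 172 at 96 h.

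Other named genes stood in the same direction at both times without passing the test. The log2 differences at 48 h and 96 h were 0.71 and 0.75 for ARPN (AT2G02850), which encodes plantacyanin, with an adjusted p of 0.0630. They were 0.71 and 1.04 for AT1G49000, 0.67 and 0.91 for AT5G05250, 0.64 and 0.90 for AT1G20070, 0.63 and 0.86 for the pectin methylesterase gene AT5G04960, and 0.63 and 0.87 for AT5G66985. On the lower side they were -0.69 and -1.40 for AT5G45310, with an adjusted p of 0.0526, -0.84 and -0.78 for AT3G22210, and -0.58 and -1.58 for AT4G24350. The xyloglucan-modifying gene XTH33 (AT1G10550) stood at -0.60 and -0.70. AT1G29670, AT2G25735, AT2G20142 and AT1G14480 lay between -0.73 and -0.55 at either time.

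In all, 27 probe sets passed the limma threshold for starvation, 17 higher and 10 lower, with mean changes from 1.72-fold to 5.47-fold. Of these, 11 had exactly 1 annotated gene and 16 had no single annotated gene. At least 2-fold differences at both times were found for 5 probe sets on the higher side and 1 on the lower side. Only AT1G73120 among these 6 had a single annotated gene. The others are given by their probe set identifier and were chosen after their values were seen. The widest difference was that of 254743_at, with 25.9 in control and 150.0 in starved roots at 48 h, and 17.0 and 233 at 96 h (adjusted p = 1.1e-05). Probe sets 254550_at, 250832_at and 261341_s_at were 2.26-fold, 2.03-fold and 2.36-fold higher at 48 h, and 2.32-fold, 2.85-fold and 2.97-fold higher at 96 h. The values of 261341_s_at on the control arrays were 3.3 and 2.3, near the floor of the measurement, as was that of AT1G73120 on the control 48 h array (4.0). Their folds depend on the pseudocount. Probe set 247925_at was 2.2-fold lower at 48 h and 2.44-fold lower at 96 h.

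Of the 27 probe sets called for starvation, 14 were also called for the difference between 96 h and 48 h, where 1.99 would be shared by independent lists. The change had the same direction in 12 of the 14. Both tests use the same estimate of spread for each probe set, which raises the overlap but does not set the direction. The named genes among the 14 were AT5G26130, PDF2.1, AT1G73120, TPS-CIN, UGT72E1 and AT4G01390. PDF2.1 rose with starvation and fell from 48 h to 96 h, and the others changed the same way in both comparisons. Why the directions mostly agreed was not tested, so for these genes starvation is not cleanly set apart from the harvest difference. Across the 13998 probe sets the log2 differences at 48 h and 96 h correlated weakly (Pearson r = 0.105, Spearman rho = 0.049, across genes, which are not independent replicates), and 50.6% had the same sign. Setting the 4 arrays against each other in the other ways gave 126 probe sets for 96 h against 48 h and 1 for opposite starvation differences, beside the 6 for starvation. The count of 27 moved with the processing: it was 5 with a pseudocount of 1, 12 after quantile normalization, 3 with equal medians, and 4 after cyclic loess normalization (3 higher and 1 lower) or with the filter at the 60th percentile. limma called 0 probe sets without the filter (1346 at an unadjusted p below 0.05), 0 without the time term (278), and 0 when the control 48 h (281), starved 48 h (671), control 96 h (232) or starved 96 h array (249) was left out. Those fits on 3 arrays also lacked the time term, so the loss cannot be put down to any single array.

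**Figure D1:**
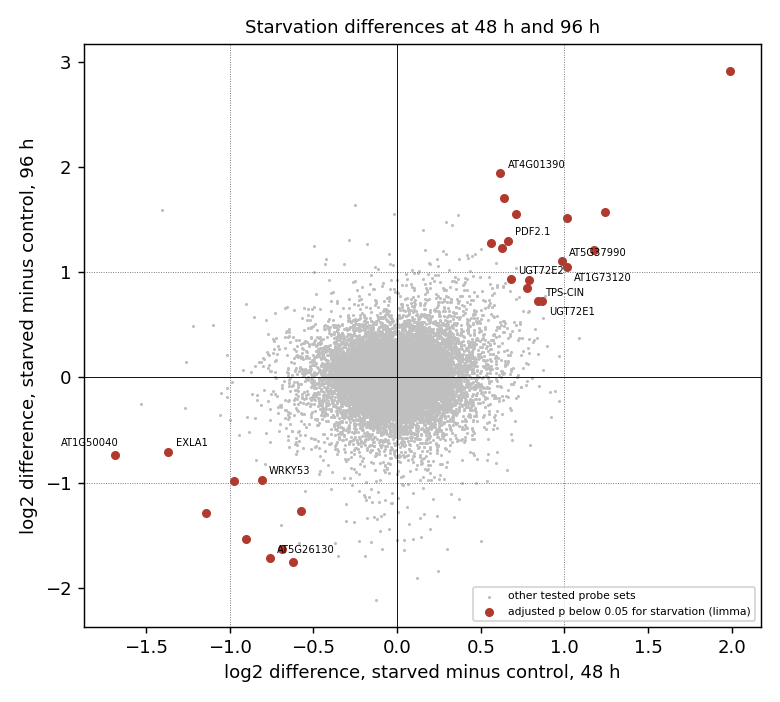
Each point is 1 of the 13998 tested probe sets, with the log2 difference between the starved and the control array at 48 h on the horizontal axis and at 96 h on the vertical axis. The 27 probe sets that limma called for starvation are red, with gene names where 1 gene is annotated. Dotted lines mark 2-fold differences, and the point at the upper right is 254743_at.

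At 48 h, EXLA1, the expansin-like cell wall gene, was among the named genes farthest below the control. It was 2.58-fold lower, with a signal of 179.5 in control and 59.9 in starved roots. AT3G19430 was 2.33-fold lower. AT1G50040 was 3.22-fold lower, and AT2G15870 and AT1G53450 were 2.4-fold lower. The starved signals of AT1G50040 (14.9), AT2G15870 (5.9) and AT1G53450 (6.2) were below the 40th percentile of that array, 29.6, so their folds depend on the pseudocount. On the higher side AT2G34670 was 2.12-fold, AT1G73120 2.02-fold and AT5G37990 1.98-fold higher. AT3G62000 was 1.88-fold and AT4G39780, an AP2/ERF transcription factor gene, 1.83-fold higher. The control signals of AT1G73120 (4.0), AT3G62000 (11.4), AT2G34670 (23.5) and AT5G37990 (25.2) were below the 40th percentile of their array, with the same limit on the folds. In all, 6 probe sets were at least 2-fold higher and 14 at least 2-fold lower, and these differences have no test because each group held 1 array. The starved 48 h array stood apart in the control probe set for 25S ribosomal RNA, with 795.5 against 58.7 to 73.1 on the other arrays. The count of 20 was 92 with a pseudocount of 1 and 1 with a pseudocount of 64, 45 without the filter and 10 with the filter at the 60th percentile.

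At 96 h, the CAP-family gene AT4G33720 had a signal of 1880.4 in control and 513 in starved roots, 3.58-fold lower. AT5G14120, of the major facilitator superfamily, had 989.6 and 294, 3.24-fold lower. ATL8 (AT1G76410), a RING-type ubiquitin ligase gene, was 3.25-fold lower, AT5G26130 3.29-fold and AT4G24350 2.98-fold lower. The starved signal of AT4G24350 was 2.1, near the floor, so its fold depends on the pseudocount. AT4G01390 was 3.84-fold higher, the chitinase-family gene AT2G43590 3.12-fold, AT4G01870 2.78-fold, PDF2.1 2.46-fold and AT2G48080 2.31-fold higher. At least 2-fold differences were counted for 119 probe sets, 50 higher and 69 lower, again with no test within the time. The control array of this time stood apart in its hybridisation controls: the CreX-3 control transcript measured 856 on it and 1758 on the starved 96 h array. A GAPDH control probe set (AFFX-r2-At-GAPDH-3_s_at) measured 1763 and 2543, and a ubiquitin one (AFFX-r2-At-Ubq-3_x_at) 2266 and 3521. Of 4 photosynthesis genes, the markers of green tissue, 3 measured lower in starved than in control roots at this time, and their median log2 difference was -0.28. The count was 227 with a pseudocount of 1 and 40 with a pseudocount of 64.

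The starvation differences were compared between the times as values, because 1 array per group leaves no residual for an interaction term. Of the genes with the widest differences at 96 h, AT4G33720 stood at a log2 difference of 0.24 at 48 h and -1.84 at 96 h, and AT2G43590 at -0.25 and 1.64. AT5G14120 stood at -0.19 and -1.70, and ATL8 at -0.35 and -1.70. Of the genes with the widest differences at 48 h, AT3G19430 stood at -1.22 and 0.49, AT1G53450 at -1.26 and 0.15, and AT3G62000 at 0.91 and -0.14. The SD of the log2 differences over all tested probe sets was 0.237 at 48 h and 0.295 at 96 h. One probe set, 265644_at, was at least 2-fold in opposite directions, with log2 differences of -1.41 and 1.59. It measured 35.2 in control and 3.3 in starved roots at 48 h, and 5.0 and 47.0 at 96 h, so the lower value of each time lay near the floor and the size depends on the pseudocount. It has no gene name here and was chosen after its values were seen.

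The comparison of 96 h with 48 h asked what differed between the harvests whatever the solution. Transcripts that low oxygen is known to induce rose at 96 h in both control and starved roots. AT3G29970 rose from 11.8 to 1161 in control roots and from 4.4 to 1353 in starved roots. AT5G10040 rose from 6.5 to 697 and from 16.5 to 966, and AT2G17850 from 31.9 to 839.9 and from 27.8 to 1401. AT3G10040, which encodes the hypoxia-response regulator HRA1, rose by 2.33 and 2.90 on the log2 scale in control and starved roots.

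The log2 changes in control and starved roots were 3.44 and 4.32 for AT4G33560, 2.81 and 3.64 for AT4G24110, 2.68 and 3.26 for AT4G10270, and 2.34 and 2.16 for AT1G33055. AT5G66985 stood at 2.14 and 2.38. The 48 h signals of AT3G29970 and AT5G10040 were near the floor, and those of AT4G33560 (17.2 and 18.6) and AT4G24110 (15.2 and 16.3) were low. Those of AT3G10040 (27.2 and 30.4) and AT2G17850 (31.9 and 27.8) lay near the 40th percentile of their arrays. On the falling side AT4G11190 measured 1.8 and 5.1 at 96 h, and XTH26 measured 14.2 and 24.3. The size of all these changes depends on the pseudocount. The adjusted p-values from limma for the 9 genes higher at 96 h ranged from 2.2e-12 to 6.9e-08. Such p-values rest mostly on a spread shared across probe sets, and each time held only 1 control and 1 starved array. They do not measure the spread between harvests. AT5G26130 fell by 3.3 in control roots and fell by 4.26 in starved roots on the log2 scale (adjusted p = 1.5e-09). The changes were -2.41 and -1.77 for PDF2.1, -1.46 and -1.96 for AT1G70880, -1.58 and -1.38 for AT4G08380, and -1.47 and -1.25 for AT4G11190, a dirigent-family gene. The root hair gene XTH26 (AT4G28850) changed by -1.33 and -1.21, AT3G57010 by -1.21 and -1.10, and the germin-like AT3G05950 by -1.08 and -2.03. All 8 genes on the lower side passed the limma threshold, with adjusted p-values of at most 0.000638.

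limma called 1029 probe sets for the difference between the harvests, 575 higher and 454 lower at 96 h. At least 2-fold changes in the same direction in both solutions were counted for 126 probe sets, 104 higher and 22 lower, and 1 probe set was at least 2-fold in opposite directions. The changes in control and starved roots correlated across genes with Pearson r = 0.594 and Spearman rho = 0.441, and 65.1% had the same sign. The count of 1029 was 655 with equal medians, 103 without the filter, 615 with the filter at the 60th percentile and 392 without the solution term. Fits on 3 arrays, which also lacked the solution term, called 23 without the control 48 h array, 30 without the starved 48 h array, 1123 without the control 96 h array and 638 without the starved 96 h array. They changed both the arrays and the model, and are to be set beside the 392 rather than the 1029.

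**Figure D2:**
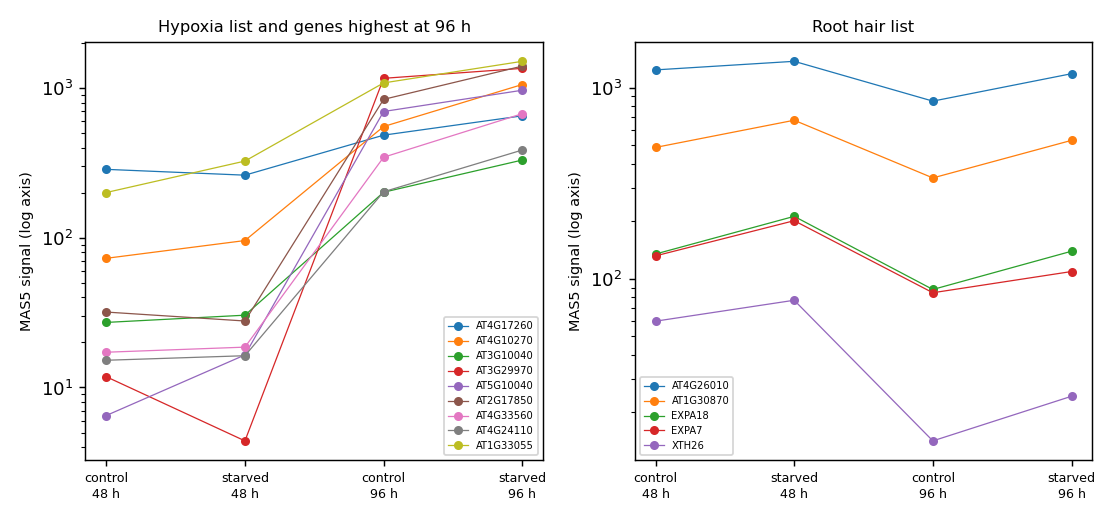
MAS5 signal on a log axis on each of the 4 arrays. On the left are the 3 measured members of the hypoxia list and the 8 named genes highest at 96 h, of which 2 are shared. On the right are the 5 measured root hair markers, which lie higher on the starved array than on the control array of the same time. Lines join the values of 1 gene, and each point is 1 array.

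Gene lists fixed before the data were examined covered nutrient responses, hormones, root cell types and handling. Root hair markers stood out in both comparisons. All 5 measured members, EXPA18 (AT1G62980), EXPA7 (AT1G12560), XTH26 and the peroxidase genes AT1G30870 and AT4G26010, were higher in starved roots at both times. The log2 differences at 48 h and 96 h were 0.60 and 0.58 for EXPA18, 0.56 and 0.32 for EXPA7, 0.46 and 0.63 for AT1G30870, 0.29 and 0.42 for XTH26, and 0.15 and 0.47 for AT4G26010. The list median was 0.46 at 48 h and 0.47 at 96 h, at the 99.99 and 99.78 percentile of 10000 random lists of the same size and mean expression. No member passed the limma threshold for starvation over all probe sets, and 3 did when adjusted over the list alone. All 5 were lower at 96 h than at 48 h in both solutions, and 3 of them, XTH26, EXPA7 and EXPA18, fell by the limma test (5 adjusted over the list alone).

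The hypoxia list had 3 measured members, AT4G10270, AT3G10040 and the lactate dehydrogenase gene AT4G17260, and all 3 rose at 96 h against 48 h (3 adjusted over the list alone). The list median changed by 2.33 in control and 2.90 in starved roots, at or above the 99.98 percentile of random lists. In starved against control roots its median was 0.10 at 48 h, at the 78.0 percentile, and 0.67 at 96 h, at the 99.89 percentile. No member passed for starvation over all probe sets, and 2 did when adjusted over the list alone. Photosynthesis genes, the markers of green tissue, had 4 measured members, RCA (AT2G39730), PRK (AT1G32060), LHCB4.1 (AT5G01530) and SBPASE (AT3G55800). RCA and PRK rose at 96 h (adjusted p = 0.0227 and 0.0345), and 2 also passed when adjusted over the list alone. The list median changed by 0.76 in control roots, at the 99.99 percentile, and by 0.32 in starved roots, at the 96.1 percentile. Against the control, starved roots had a median of 0.20 at 48 h (95.9 percentile) and -0.28 at 96 h (1.65 percentile). LHCB4.1 measured 183 in control and 218 in starved roots at 48 h, and 336 and 198 at 96 h.

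The other lists had at most 2 measured members, that is, named members past the filter. None of these passed the limma threshold for starvation over all probe sets. Only 51 of the 536 listed genes had a named probe set, so a response of unnamed members would not be seen here. CML38 was the only measured member called for the difference between the harvests over all probe sets. Adjusted over the list alone, 1 member each of the auxin, iron, potassium regulator and zinc lists also passed. For lists with 1 measured member that is no adjustment. The log2 differences at 48 h and 96 h were 0.37 and 0.73 for AT3G13610, a coumarin synthesis gene (F6H1) of the iron deficiency list, and 0.09 and 0.44 for the iron regulator PYE (AT3G47640). AT3G13610 passed when adjusted over its list alone, with 1 of 2 members. The differences were 0.33 and 0.38 for the dehydrin gene COR47 (AT1G20440), the 1 measured member of the abscisic acid list (adjusted p = 0.598 from limma over all probe sets). COR47 passed when adjusted over its list alone, which for 1 member is no adjustment. ZIP9 (AT4G33020) of the zinc list stood at 0.24 and 0.35, SAMDC (AT3G02470) of the polyamine list at 0.16 and 0.39, and the low-pH gene AT1G51340 at 0.02 and 0.33. The potassium uptake regulator bHLH121 (AT3G19860) stood at 0.30 and -0.33, CHX16 (AT1G64170) of the cation/proton antiporters at -0.08 and -0.14, and the nitrate list's AT2G26690 at -0.06 and -0.02.

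In the ethylene list EIN3 (AT3G20770) stood at 0.01 and -0.45 and RTE1 (AT2G26070) at -0.14 and -0.26. WES1 (AT4G27260) of the auxin list stood at 0.08 and 0.15, UGT78D2 (AT5G17050) of flavonoid synthesis at -0.03 and -0.17, and BCAT4 (AT3G19710) of glucosinolate synthesis at 0.15 and -0.78. The phloem marker SWEET11 (AT3G48740) stood at -0.07 and 0.16, the mitotic kinase gene AUR1 (AT4G32830) at -0.22 and -0.17, and the heat shock list's AT5G48570 at 0.48 and -0.15. The evening clock gene GI (AT1G22770) stood at 0.17 and 0.14 for starvation, and at 0.33 and 0.30 for 96 h against 48 h in control and starved roots. Of the touch and wounding list, CML38 (AT1G76650), which low oxygen is also known to induce, rose at 96 h by 1.45 and 2.63 (adjusted p = 9.4e-06), and STZ (AT1G27730) stood at -0.01 and -0.14. No named member of 13 lists passed the filter. The KUP/HAK/KT transporters, sulfate, jasmonate and cytokinin lists had named probe sets, all below the filter. Potassium channels, phosphate, reactive oxygen, aquaporins, proton pumps, the endodermal barrier, xylem, morning clock genes and constitutive control genes had no named probe set. For the lists without a named probe set the lack of a result is a lack of names and not a measured lack of signal or response.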

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

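The tests of array scaling, low oxygen and time of day below were chosen after the results were seen, while the test of array noise was chosen before its value was seen. Of data outside the comparisons, the control probe set for 25S ribosomal RNA (AFFX-Athal-25SrRNA_s_at) measured 795.5 on the starved 48 h array, against 58.7 on the control 48 h, 73.1 on the control 96 h and 60.8 on the starved 96 h array. Probe set 265644_at had log2 differences of -1.41 at 48 h and 1.59 at 96 h between starved and control roots. Its signals were 35.2 and 3.3 in control and starved roots at 48 h, and 5.0 and 47.0 at 96 h, near the floor, so the size depends on the pseudocount. It drew attention because the 2 times went opposite ways, and the difference was not tested.

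Genes associated with hypoxia were higher at 96 h than at 48 h in both solutions. The choice of scaling did not account for this: the median change of 23 measured core hypoxia genes, listed afterwards, was at least 1.79 on the log2 scale in either solution under the main scaling and 3 others. All these scalings make the bulk of each array alike. Part of the 23 had already been named, most of those for their rise at 96 h, and the range over scalings was not taken for the rest of that list. A low oxygen supply in the roots harvested at 96 h is a candidate explanation: the 13 members of that list that no rule had named had medians of 1.37 in control and 1.48 in starved roots, at the 100 percentile of random lists in both. Time of day stays open, since only 1 clock gene was measured, GI, with a change of at most 0.33. Harvests at exactly 48 h and 96 h after a common transfer would fall at the same hour of day, but neither condition was checked. Markers of tissue moved between the harvests as well. The median of the photosynthesis list rose by 0.76 in control and 0.32 in starved roots, and that of the 5 root hair markers changed by -0.54 and -0.55. A difference in the tissue sampled was not tested. The time in the fresh solution, a group of the design, was not tested apart from the harvest, and transcripts do not measure oxygen.

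Starvation differences were larger at 96 h than at 48 h, with a ratio of SDs of 1.25 over the tested probe sets. Noise that acts on all probe sets would widen dim ones as well. Among the 8748 probe sets below the filter the ratio was 0.95 (95% bootstrap interval over probe sets 0.928 to 0.977). This argues against noise of that kind as the whole cause. Dim probe sets cannot show noise that acts on brighter ones, so that stays open. The interval is over probe sets of 1 pair of arrays per time, and does not measure the spread between arrays. A longer starvation may widen the response, but a difference in tissue or in hybridisation between the 96 h arrays stays open, since no group had a second array. The CreX-3 control transcript measured 856 on the control 96 h array, and 1495 to 1758 on the others.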

How the results depend on the processing

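The alternatives without time-called probe sets were chosen after seeing the data, and all others before. No paired analysis was possible because the groups share only replicate number 1. The time term of the main model sets each starved array against the control of its own time, and this is not a pairing of replicates. Leaving out an array leaves no value for the counts over both times. Of the 79 named genes, 2 changed the sign of their mean starvation difference under some normalization, pseudocount or filter, and none of the 11 called ones did. None of these 11 passed under every alternative: all 11 lost the call with a pseudocount of 1, equal medians, cyclic loess or no filter, 7 with quantile normalization, and 1 with a pseudocount of 64. With equal medians, cyclic loess and no filter, the mean difference of UGT72E1 was 0.795, 0.827 and 0.798, beside 0.798 in the main setting. The prior degrees of freedom were 8.563, 9.138 and 4.799, beside 14.94. The calls thus rest on the shared estimate of spread. The 60th percentile filter left 7 of the 11 in the test, and all 7 lost the call. Of the 31 named genes called for 96 h against 48 h, 16 passed under every such alternative that tested them. The call was lost by 15 without the filter, by 7 each with equal medians and cyclic loess, by 6 with a pseudocount of 1 and by 3 with quantile normalization. The 60th percentile filter left 25 of the 31 in the test, and 3 of these lost it.

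With a pseudocount of 1, the counts of at least 2-fold differences were 15 at both times, 92 at 48 h, 227 at 96 h, 202 for 96 h against 48 h in both solutions and 3 in opposite directions. With 64 they were 1, 1, 40, 66 and 0. A fold threshold of 1.5 gave 52, 326, 713, 487 and 11, and a threshold of 3 gave 1, 2, 16, 41 and 0, by construction. At 48 h the count was 45 without the filter and 10 with the filter at the 60th percentile, and the opposite directions gave 2 and 0. Without probe sets that limma called for time, 2 were left at both times and limma called 7 for starvation.

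limma's starvation calls, 27 in the main setting, numbered 5 with a pseudocount of 1, 12 after quantile normalization, 3 with equal medians, 4 after cyclic loess and 4 with the 60th percentile filter. They were 0 without the filter (1346 at an unadjusted p below 0.05), 0 without the time term (278), and 0 with each array left out in turn (232 to 671). The fits without an array also lacked the other term, so they changed 2 choices at once, and a lone array was assumed to vary like the others. The time calls, 1029 in the main setting, numbered 655 with equal medians, 103 without the filter, 615 with the 60th percentile filter and 392 without the solution term. They ranged from 23 to 1123 with each array left out, lowest without the control 48 h array. Apart from the fold thresholds, the cause was not tested.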

Other observations

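The lists of core hypoxia genes and of further root hair genes, and the scan of gene families, were made after the main results were seen. The tests of scaling and of low oxygen were also chosen afterwards, while the test on further root hair genes was chosen before their values were seen. Of 45 core hypoxia genes listed from general knowledge, 23 were measured. By the limma test 22 of them rose at 96 h against 48 h (22 adjusted over the list alone). Part of the 23 had already been named, most of those for their rise at 96 h, so this count partly restates that choice. Of the 13 members that no rule had named, 12 rose by the limma test. PDC2, a pyruvate decarboxylase gene of ethanol fermentation, had 519 and 667 in control and starved roots at 48 h, and 1331 and 1688 at 96 h (adjusted p = 3.2e-05). AT3G03270, a universal stress protein gene, had 404 and 566 at 48 h, and 1850 and 2693 at 96 h. In starved against control roots, 16 of the 23 genes were higher at both times and 0 were lower at both. The list median was 0.13 at 48 h (99.4 percentile) and 0.54 at 96 h (100 percentile). No member passed the limma threshold for starvation over all probe sets, and 13 did when adjusted over the list alone. Among the 13 members that no rule had named, 9 were higher and 0 lower at both times, and 7 passed when adjusted over those members alone. CML38 of the touch and wounding list is also among the 23.

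A scan of 28 families of named genes with at least 6 measured members, by the stem of their symbols and over 4 comparisons each, gave 2 whose medians lay below the 1st percentile of random lists for 96 h against 48 h in both solutions. The xyloglucan endotransglucosylase/hydrolase genes (XTH, 7 members) had medians of -0.45 in control and -0.53 in starved roots, and 5 were lower in both. The serine carboxypeptidase-like genes (SCPL, 16 members) had -0.33 and -0.26, with 11 lower in both. Both directions held under the 4 scalings. For starvation, 2 families lay above the 99th percentile, each at 1 time only, and none lay below the 1st. The stem CYP joined 7 cytochrome P450 genes with 2 cyclophilin genes, CYP71 and CYP59, and had a median of 0.23 at 48 h (99.65 percentile) and 0.04 at 96 h (68.1 percentile), and the lowest 48 h median over the 4 scalings was 0.23. The alpha-expansins (EXPA, 6 members) had a median of 0.10 at 48 h (88.2 percentile) and 0.46 at 96 h (99.99 percentile). EXPA7 and EXPA18 belong to this family and to the root hair list.

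Root hair markers were higher on the starved array at both times. The choice among the 4 scalings did not account for this: the lowest median of the 5 markers over both times and 4 scalings was 0.37. All 4 make the bulk of each array alike, so a shift of most transcripts would not show. The CreX-3 control transcript measured 1495 on the control and 1723 on the starved array at 48 h, and 856 and 1758 at 96 h. No scaling to such added transcripts was tried. A test on other root hair genes asked whether the difference extended beyond the 5 markers. The 7 measured of 22 such genes had medians of 0.46 at 48 h and 0.75 at 96 h, and the lower of their percentiles was 99.99. The 96 h median is the value of AT3G54580, which stood below the control at 48 h. These genes extend the pattern on the same 4 arrays and do not test its cause. No member passed the limma threshold for starvation over all probe sets, and whether hairs were more frequent or more of the hair zone was sampled was not tested.

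Of the 7 other root hair genes, 5 were higher at both times, while the extensin-family genes AT5G06630 and AT3G54580 stood at -0.43 and -0.29 at 48 h and at 1.13 and 0.75 at 96 h. For 96 h against 48 h, AT5G06630 rose by 0.89 and 2.45 in control and starved roots (adjusted p = 0.000458 from limma). AT3G54580 rose by 1.51 and 2.54 (adjusted p = 5.5e-06), while the other 5 genes were lower in both solutions. The probe set of AT5G06630, 250682_x_at, is of a type that can also bind related transcripts, so which gene it measured is uncertain.

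Hybridisation control transcripts added to each sample were dimmest on the control 96 h array. The probe set AFFX-CreX-3_at measured 1495 on the control 48 h, 1723 on the starved 48 h, 856 on the control 96 h and 1758 on the starved 96 h array. The change of the 5' probe set relative to the 3' probe set, on the log2 scale, was 0.07 at 48 h and 0.15 at 96 h for actin, -0.20 and 0.11 for GAPDH, and 0.33 and -0.22 for ubiquitin, in starved against control roots.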
